A study of Mus musculus with 3 samples.

How the data were processed

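Liver and spleen RNA of the mouse were compared on 3 cDNA arrays, each hybridised with both tissues. Per the labels, both total RNAs were commercial catalogue preparations, amplified in a double round to cRNA before labelling, with spleen in Cy3 (green) and liver in Cy5 (red) on each array. The labels number the arrays as replicates 1, 2 and 3 and do not say whether they came from separate animals, RNA lots or amplifications. The p-values of single genes and spots therefore measure only the spread between these arrays, which may be technical. No array had the dyes exchanged, so a dye effect and a tissue effect cannot be told apart.

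The values deposited by the authors were 1 log2 ratio of the 2 channels per spot and array. The log base was taken from the values, whose upper limit equalled the log2 of 100 and was reached by 2 values. The authors' background correction, normalization and spot filters are not given in the sources used here, and the centring and scale of the ratios are known only from the values. The median over all 16273 spots was 0 on each array, and over the spots with a value it was -0.02, 0.03 and 0.05 on arrays 1, 2 and 3. An exact 0 was listed for 3207, 5153 and 1063 spots, whereas no other value occurred more than 2 times on an array. Of the spots at exact 0 on at least 1 array, 860 had an absolute log2 ratio of at least 1 on another. An exact 0 was therefore treated as a missing ratio, a choice made on seeing the values, and the alternative of keeping it as 0 was run. Channel intensities were not used here, so the signal over background behind a ratio is unknown.

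The channel in the numerator is not given in the sources used here. The sample titles name spleen before liver ("D-Spleen vs D-Liver") without saying which is the numerator. The sign was set from a liver list and a spleen list fixed for that purpose, of which Fgb and Ttr (liver) and Ms4a1, Ighm and Coro1a (spleen) had values. The lists' medians lay on opposite sides on all 3 arrays: 4.55, 4.99 and 2.52 for the liver list, and -3.06, -3.57 and -2.53 for the spleen list. Positive ratios are thus likely liver over spleen, and these lists are not evidence of direction.

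Spots were named from the platform annotation, with symbols updated by Entrez identifier through RefSeq names of the assembly GRCm38.p6; 12228 of 12397 annotated spots matched. A single gene was named for 12336 spots, several genes for 61 and no gene for 3876, and only the first kind entered gene tests. No coordinates were used. Spots of a gene were averaged on each array over those with a value. Of 7984 named genes, the 5731 with a value on all 3 arrays were tested, and 2270 of these had more than 1 spot.

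Mean log2 ratios were tested against 0 with limma 3.58.1 in R 4.3.3 (an intercept fitted with lmFit, then eBayes; two-sided). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. A fit to 3 arrays leaves 2 residual degrees of freedom per gene; eBayes added 3.51 prior degrees of freedom with a prior SD of 0.24. The smallest two-sided p that an exact sign-flip test on 3 arrays can give is 0.25, so no such test was used. The fit was tested on simulated data with 5731 genes, of which 50 were changed at each size. At log2 ratios of 0.5, 1, 2 and 4 it recovered 4%, 66%, 92% and 98% of the changed genes, with 4 false calls. Only 200 genes were changed and noise was drawn independently per gene, whereas 54.9% of tested genes were called in the data. The recovered shares therefore do not give the power at these sizes in the data. Errors are SD over the 3 arrays, and the number of arrays limits the precision. For a gene with more than 1 spot, the SD can also reflect which spots had a value on each array. This may hold for Fgb, Mt1 and Car2, whose ratios shrank with exact zeros as values.

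The gene lists covered plasma and coagulation proteins, complement, acute-phase proteins, drug metabolism, lipid, sterol and bile acid metabolism, fatty acid oxidation, amino acid and urea cycle metabolism, carbohydrate metabolism, and major urinary proteins. Other lists held markers of B cells, T and NK cells, macrophages and dendritic cells, neutrophils, erythroid cells, megakaryocytes and platelets, stroma, endothelium, pancreas, muscle, adipose tissue and brain. The remaining lists covered MHC class I, MHC class II, chemokines and cytokines, the interferon response, the cell cycle, ribosomal proteins, oxidative phosphorylation, the proteasome, endoplasmic reticulum and secretion, stress genes, and the actin cytoskeleton of blood cells. Lists with at least 5 measured genes were tested with limma's cameraPR, called camera below, at a preset correlation of 0.01, adjusted over 24 lists. It took signed z-scores made from the per-gene p-values. Its p-values thus compare genes in a list with other genes. They take genes rather than arrays as units and do not measure the spread between arrays. The version with an estimated correlation was camera itself on the log2 ratios. At the preset correlation the 2 functions gave close values, such as adjusted p = 9.03e-07 (cameraPR) and 9.01e-07 (camera) for plasma proteins. The lists, tests and thresholds, and the rule for named genes, were set before the data were examined.

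That rule took the 12 called genes with the largest mean ratio on each side and the same sign on all 3 arrays, then up to 4 called members with the largest absolute ratio per list. For a list with no called member it took the member with the largest absolute ratio. It also took Actb, Gapdh, Hprt, B2m and Tbp as common reference genes. List members outside the rule are named where they opposed their list, were not called or served as further examples, and were chosen after their values were seen.

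The settings varied were centring each array, scaling the arrays to one spread, a value on at least 2 arrays, the largest spot per gene, a test per spot, each gene's ordinary variance, trended robust variance, and leaving out each array in turn. Also run were limma's treat against a 2-fold change, camera with an estimated correlation, and fry. Keeping exact zeros as values, averaging only spots valued on all arrays, and leaving out clones whose sequence identifier starts with AW or AU were added after seeing the data; the other settings were listed beforehand.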

Results

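RNA of mouse liver and spleen was compared on 3 two-colour cDNA arrays, which form 1 group: each array carried double-round amplified spleen RNA in Cy3 and liver RNA in Cy5. The comparison asks which transcripts differ in abundance between the 2 tissues after this amplification. Of 16273 spots, 13066, 11120 and 15210 had a ratio on arrays 1, 2 and 3, with SDs over spots of 1.12, 1.22 and 0.98 (log2). Positive log2 ratios are called liver over spleen throughout. This direction is likely rather than stated, and rests on fibrinogen beta (Fgb) and transthyretin (Ttr, array 1 only) on 1 side, and on the B-cell genes Ms4a1 and Ighm and the leukocyte gene Coro1a (arrays 1 and 2) on the other. Scale and centring are those of the deposited ratios.

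With all spots of a gene averaged, Slc47a1, an exporter of organic cations, had the largest log2 ratio on the liver side, 6.01 ± 0.32 (SD, n = 3 arrays), or 64.4-fold higher in liver (limma adjusted p = 2.75e-05). Aadac, an arylacetamide deacetylase, followed at 5.85 ± 0.10, Baat, which conjugates bile acids, at 5.68 ± 0.27, and coagulation factor F11 at 5.65 ± 0.22. Gldc, the glycine decarboxylase of the glycine cleavage system had a mean of 5.66 ± 1.06, in which 1 spot with a value on array 3 only (0.24) lowered the mean and widened the SD. Its other 2 spots averaged 6.26 and 6.47, both above Slc47a1 and each with 1 value at the upper limit of 100-fold. Gstm6 (5.38 ± 0.11), the sulfotransferase Sult1d1 (5.38 ± 0.42), Mtarc1 (5.30 ± 0.35), the methyltransferase Gnmt (5.29 ± 0.25), the apolipoproteins Apoc3 (5.21 ± 0.38) and Apoh (5.16 ± 0.17), and the peroxisomal reductase Pecr (4.96 ± 0.21) made up the leading 12.

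On the spleen side Cd83, a surface protein of activated dendritic and B cells, had a log2 ratio of -4.01 ± 0.14 (16.1-fold higher in spleen, adjusted p = 3.18e-05). Ms4a1, which encodes the B-cell antigen CD20, stood at -3.93 ± 0.39, and Jchain, the joining chain of secreted IgM and IgA, at -3.45 ± 0.51. Ngp, a neutrophil granule protein, stood at -3.68 ± 0.31. Pbk (-3.63 ± 0.45), the cyclin-dependent kinase Cdk1 (-3.49 ± 0.35) and the kinetochore protein Knl1 (-3.47 ± 0.55) act in mitosis. The phosphodiesterase Pde7a (-3.88 ± 0.84), the actin-binding Synpo2 (-3.72 ± 0.19), Ms4a6b (-3.52 ± 0.50), the long non-coding RNA Lockd (-3.45 ± 0.44) and the glycosyltransferase Gcnt1 (-3.43 ± 0.45) completed the 12.

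**Figure D1:**
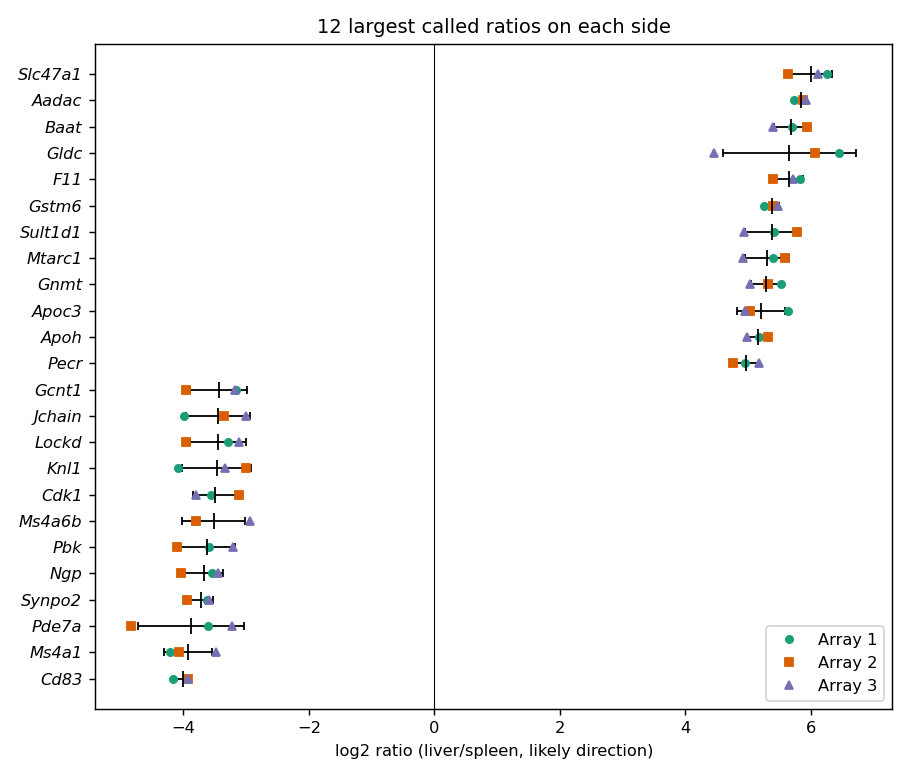
Log2 ratio of liver over spleen (likely direction) for the 12 called genes with the largest mean ratio on each side. Symbols are the 3 arrays, vertical ticks the mean and horizontal bars the SD; liver-side means run from 4.96 (Pecr) to 6.01 (Slc47a1) and spleen-side means from -4.01 (Cd83) to -3.43 (Gcnt1).

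In all, 3146 of 5731 genes (54.9%) differed at an adjusted p under 0.05, 1551 higher in liver and 1595 higher in spleen, and none of them had mixed signs over the arrays. At least 2-fold differences were found for 1448 of these genes, 768 higher in liver and 680 in spleen. The larger differences lay mostly on the liver side: 112 genes reached a log2 ratio of 3 against 30 at -3, and 39 reached 4 against 1 (Cd83) at -4. The smallest absolute ratio called was 0.34, and the median over called genes was 0.93. Without array 1 the number of calls fell to 1841, and with each gene's own variance in place of the moderated one it was 1461. When a 2-fold difference itself was tested (limma treat), 692 genes passed, 419 on the liver side and 273 on the spleen side.

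The arrays resembled one another closely. Across genes, which are not independent replicates, Pearson's r was 0.916 for arrays 1 and 2, 0.937 for arrays 1 and 3, and 0.884 for arrays 2 and 3, with Spearman's rho of 0.865, 0.896 and 0.836. The median SD over arrays was 0.22 per gene, and its 90th percentile 0.54. The sign was shared by all 3 arrays for 4347 genes (75.9%), where chance would give 25%. Among genes commonly used as references, Hprt had a log2 ratio of 0.10 ± 0.12 (adjusted p = 0.513). B2m, the light chain of MHC class I, was higher in liver at 0.48 ± 0.23 (adjusted p = 0.0311), a call that was lost without array 1 (adjusted p = 0.201) or array 3 (adjusted p = 0.108) and under its own variance (0.135), with adjusted p from 0.00949 to 0.201 over its alternatives. With exact zeros as values, B2m fell to 0.24 (adjusted p = 0.112), as 1 of its 2 spots had no ratio. Gapdh had a ratio on array 3 only, of 0.83, and Actb and Tbp had no named spot that could be tested.

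**Figure D2:**
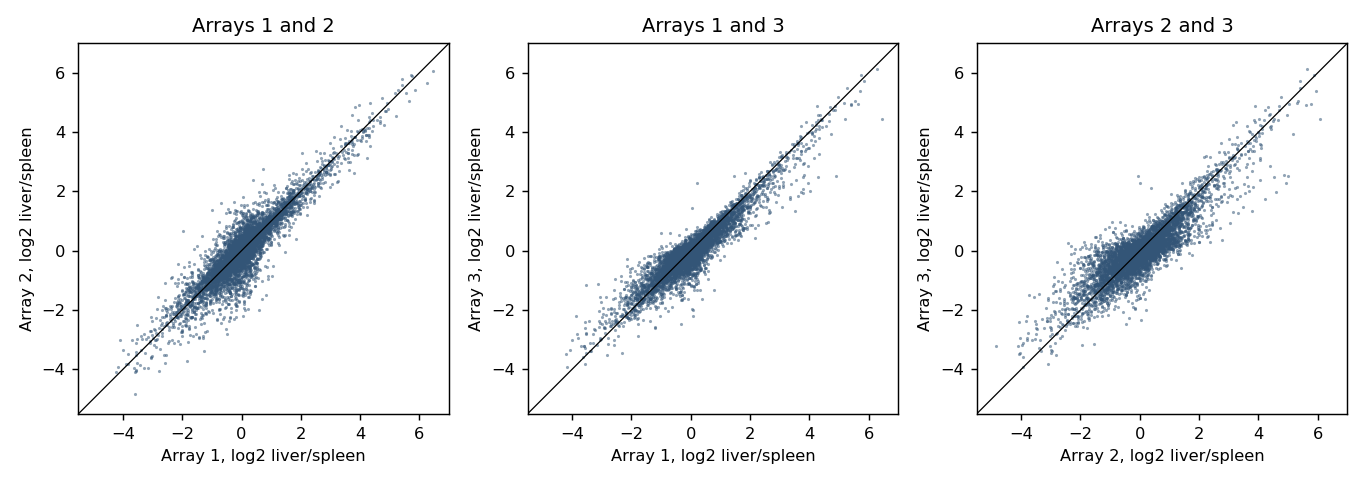
Mean log2 ratio of each tested gene (liver over spleen, likely direction) on 1 array against another, for the 3 pairs of arrays. Each point is 1 of 5731 genes and the line marks equal values; r is 0.916 for arrays 1 and 2, 0.937 for arrays 1 and 3 and 0.884 for arrays 2 and 3.

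Genes for secreted plasma proteins and for detoxification were higher in liver without exception among those measured. All 9 plasma and coagulation genes were called on the liver side (median log2 ratio 3.88), among them F11, Apoh, vitronectin (Vtn, 4.61 ± 0.63) and the retinol carrier Rbp4 (3.88 ± 0.16). All 11 drug metabolism genes were also called there (median 3.68), including the glutathione transferase Gsta3 (4.73 ± 0.41), nicotinamide N-methyltransferase Nnmt (4.48 ± 0.14) and the monooxygenase Fmo5 (4.28 ± 0.16). The single complement gene measured, C1ra, had a ratio of 2.16 ± 0.13, and the single acute-phase gene, Saa3, 2.85 ± 0.11. Both were called, and no major urinary protein gene was measured. Camera gave adjusted p = 9.03e-07 for the plasma list and 7.06e-07 for drug metabolism, and adjusted p = 0.344 with an estimated correlation for both.

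Intermediary metabolism was likewise higher in liver, with a few members on the other side. Of 16 lipid, sterol and bile acid genes, 13 were higher in liver and 2 in spleen (median 3.08); the fatty acid elongase Elovl2 stood at 4.82 ± 0.11, the triglyceride-forming Dgat2 at 3.97 ± 0.26 and apolipoprotein E (Apoe) at 3.49 ± 0.16. The 2 on the spleen side were Mttp, which loads lipid onto apolipoprotein B (-0.87 ± 0.20), and the liver fatty acid-binding protein Fabp1 (-0.44 ± 0.18). Each was measured by a single clone, so no other clone could check its side. Lipoprotein lipase Lpl was not called (0.13 ± 0.37). Of 18 amino acid and urea cycle genes, 16 were higher in liver and 2 in spleen (median 3.34). Histidine ammonia-lyase Hal (4.33 ± 0.14) and Nags, which makes the activator of urea synthesis (4.15 ± 0.22), were among the former. The alanine aminotransferase Gpt (-0.84 ± 0.19, from a single clone) and the creatine-synthesis enzyme Gatm (-0.83 ± 0.17) were the latter. Of 10 fatty acid oxidation genes, 9 were higher in liver (median 2.27), led by Bdh1 of ketone body metabolism (4.19 ± 0.30) and Decr1 (4.06 ± 0.07), while the sterol carrier Scp2 averaged -1.08 ± 0.65 through 1 AW clone (-2.48), against 2.96 for an AK clone. Of 4 carbohydrate genes, 3 were higher in liver, including ketohexokinase Khk (4.21 ± 0.09) and malic enzyme Me1 (2.92 ± 0.19), and transketolase Tkt was not called (0.44 ± 0.36). With 4 members the carbohydrate list had no list test. Camera gave adjusted p = 4.55e-06, 1.80e-06 and 0.000381 for the lipid, amino acid and fatty acid oxidation lists, and adjusted p = 0.344 with an estimated correlation for each.

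Most lymphoid genes were higher in spleen. Of 14 B-cell genes, 12 were higher in spleen and none in liver (median -2.62; camera adjusted p = 1.21e-05, adjusted p = 0.344 with an estimated correlation), including the coactivator Pou2af1 (-3.41 ± 0.14), the tetraspanin Cd53 (-3.38 ± 0.51) and the complement receptor Cr2 (-3.30 ± 0.95). Xbp1 (0.25 ± 0.16) and Ebf1 (-0.21 ± 0.28) were not called. The list shares Ms4a1 and Ighm with those that set the direction. Of 9 T and NK cell genes, 7 were higher in spleen and 2 in liver (median -1.95; camera adjusted p = 0.0154, adjusted p = 0.348 with an estimated correlation). The T-cell receptor subunit Cd3g (-3.13 ± 0.62) and the co-receptor Cd8a (-2.90 ± 0.29) were higher in spleen. Another subunit, Cd3d (1.24 ± 0.16), and the cytokine receptor Il2rb (0.53 ± 0.13, through 1 of its 2 clones) were higher in liver. Cd3g and Cd3d were each measured by a single spot, so their opposite sides could not be checked on further spots. All 3 MHC class II genes measured were higher in spleen, namely the class II transactivator Ciita (-1.59 ± 0.31), H2-Oa (-1.54 ± 0.36) and the invariant chain Cd74 (-1.24 ± 0.53), of which Cd74 lost its call without array 1 (adjusted p = 0.0534, from 0.000454 to 0.117 over its alternatives). Of 5 MHC class I genes only B2m was called, and none adjusted over the list alone (median 0.22; camera adjusted p = 0.568).

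Myeloid, erythroid and platelet genes were also mostly higher in spleen. Of 11 macrophage and dendritic genes, 8 were higher in spleen and 1, the lysosomal protease Ctsz (0.76 ± 0.39), in liver (median -1.40; camera adjusted p = 0.00192, adjusted p = 0.344 with an estimated correlation). The receptor kinase Axl (-2.14 ± 0.06), galectin-3 (Lgals3, -1.94 ± 0.21) and the iron exporter Slc40a1 (-0.89 ± 0.09) were among the 8. Of 18 erythroid and haem genes, 12 were higher in spleen and 1 in liver (median -0.78; camera adjusted p = 0.00192, adjusted p = 0.344 with an estimated correlation). Alpha globin (Hba-a1, -2.21 ± 0.25) and beta globin (Hbb-bs, -1.62 ± 0.40) were higher in spleen, as were carbonic anhydrase Car2 (-2.45 ± 0.44, or -1.55 with exact zeros as values) and the transcription cofactor Lmo2 (-2.50 ± 0.21). The haem synthesis enzyme Alas2, measured by a single clone, was higher in liver (0.91 ± 0.59). Globin paralogs are near-identical, and cDNA spots may not tell them apart. Of 5 neutrophil genes, Ngp, the calprotectin subunit S100a9 (-3.21 ± 0.76) and the receptor Csf3r (-1.07 ± 0.16) were higher in spleen and 2 were not called (camera adjusted p = 0.0134, adjusted p = 0.344 with an estimated correlation). That list was lost without array 1 (0.0932), with values on at least 2 arrays (0.0717) and with exact zeros as values (0.124), and its adjusted p started at 0.00477 over the alternatives at the preset correlation. All 4 megakaryocyte and platelet genes were higher in spleen (median -1.53, no list test), with the platelet tubulin Tubb1 at -3.22 ± 0.35; Clec1b (-0.48 ± 0.28) lost its call without array 1 (adjusted p = 0.211) or array 3 (adjusted p = 0.144), with scaled arrays (0.0550), with exact zeros as values (0.0843) and under its own variance (0.166), with adjusted p from 0.00667 to 0.211 over its alternatives.

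Most cell division and ribosomal protein genes were higher in spleen, and most mitochondrial respiratory genes in liver. Of 32 cell cycle genes, 23 were higher in spleen and 3 in liver (median -1.53; camera adjusted p = 3.3e-06, adjusted p = 0.344 with an estimated correlation). Besides Cdk1, cyclin A2 (Ccna2, -2.79 ± 0.51), the condensin subunit Smc2 (-2.72 ± 0.19) and the kinesin Kif22 (-2.93 ± 0.56) were higher in spleen, and H2az1 (1.27 ± 0.08), E2f1 (0.45 ± 0.17) and Ccnd3 (0.43 ± 0.07) were higher in liver. H2az1 was measured by AW clones only, E2f1 by a single clone, and Ccnd3 by clones that opposed each other. Of 59 ribosomal protein genes, 39 were higher in spleen and 4 in liver (median -0.56; camera adjusted p = 3.09e-06, adjusted p = 0.344 with an estimated correlation), with Rpl12 at -1.27 ± 0.19 and Rpl5 at -1.18 ± 0.06. Rpl35a was higher in liver (1.21 ± 0.15), but its mean was -0.36 (adjusted p = 0.164, the highest over its alternatives, which start at 0.000124) without the AW clones. Rpl32 (0.48 ± 0.06) was higher in liver through its AW spots alone, with a mean of -0.50 over its AK clones, and Rpl27a (0.82 ± 0.16) had AK clones on both sides. Such clones also bore on the spleen side. Rpl27 (-1.15 ± 0.16) shrank to -0.39 without AW and AU clones (limma adjusted p = 0.0448). Of 47 oxidative phosphorylation genes, 44 were higher in liver and 1, Cox6a1 (-0.79 ± 0.18, through 1 AU clone, against 1.56 for an AK clone), in spleen (median 1.57; camera adjusted p = 2.37e-13, adjusted p = 0.344 with an estimated correlation). Uqcr10 (2.30 ± 0.24), Sdhb (2.13 ± 0.23) and Ndufa9 (2.03 ± 0.12) belong to respiratory complexes III, II and I. Array scaling cannot turn a sign, and centring took off array medians of only -0.02, 0.03 and 0.05, so neither setting tests these 3 directions.

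Most proteasome genes and 15 of 26 secretory genes were higher in liver, and most actin regulators in spleen. Of 16 proteasome genes, 12 were higher in liver and 1 in spleen (median 0.70; camera adjusted p = 0.00132, adjusted p = 0.344 with an estimated correlation), led by the core subunits Psmb7 (1.55 ± 0.11) and Psmb5 (1.31 ± 0.22). Of the 26 endoplasmic reticulum and secretion genes, 3 were higher in spleen and 8 were not called (median 0.69; camera adjusted p = 0.0059, adjusted p = 0.344 with an estimated correlation). Sar1b, a GTPase of COPII vesicles, stood at 2.89 ± 0.11 and the cargo receptor Lman1 at 1.24 ± 0.11, against -1.17 ± 0.39 for Sec22b (-2.65 with its largest spot). Of 15 genes of the blood-cell actin cytoskeleton, 13 were higher in spleen and none in liver (median -0.83; camera adjusted p = 1.48e-05, adjusted p = 0.344 with an estimated correlation), including thymosin Tmsb4x (-2.22 ± 0.10) and Arpc1b (-1.78 ± 0.30).

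**Figure D3:**
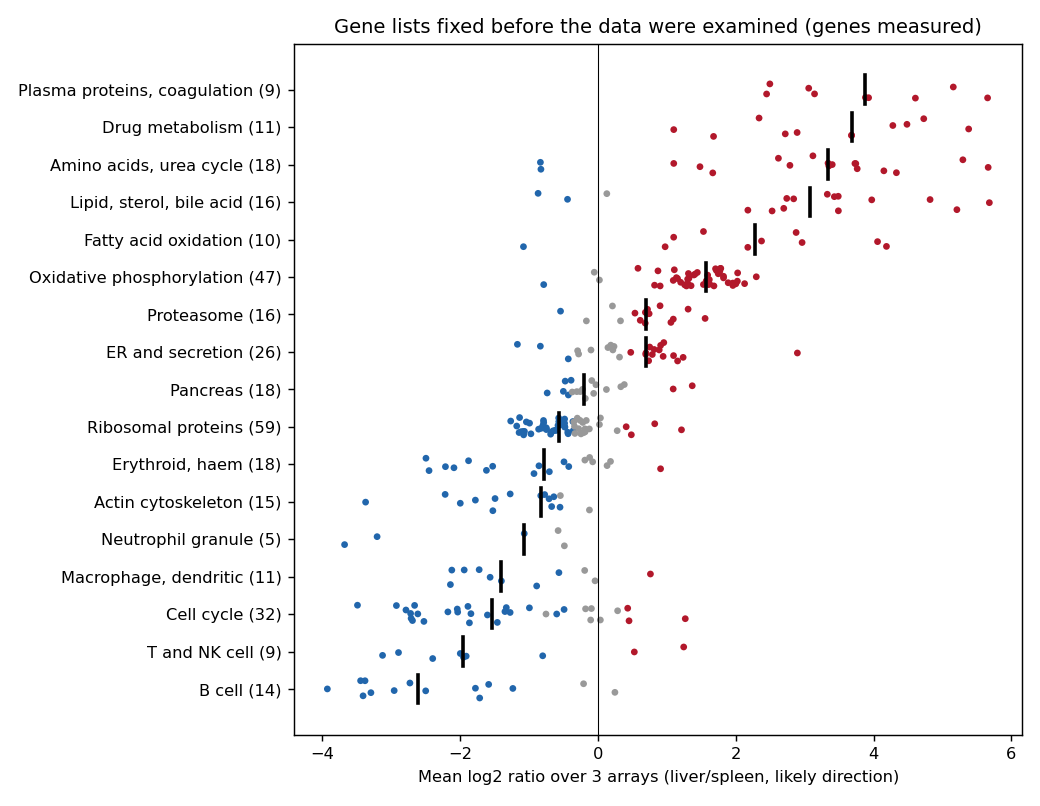
Mean log2 ratio over 3 arrays (liver over spleen, likely direction) of the members of the lists past the camera threshold, apart from chemokines, and of the pancreas list for comparison. Points are genes (red, called higher in liver; blue, called higher in spleen; grey, not called), black ticks are list medians, and the number measured stands beside each name; medians run from 3.88 for plasma proteins to -2.62 for B cells.

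Stromal, interferon response and stress genes went both ways. Of 19 stroma and matrix genes, 5 were higher in liver and 10 in spleen, with a median of -0.49 but a mean of 0.01 (camera adjusted p = 0.469). The collagen Col18a1 (3.81 ± 0.12), Igfbp4 (3.26 ± 0.53) and the proteoglycan Lum (2.82 ± 0.21) were higher in liver, and vimentin (Vim, -1.94 ± 0.26) and smooth muscle actin (Acta2, -1.47 ± 0.14) in spleen. Of 9 interferon response genes, 3 were higher in liver and 4 in spleen (median 0.02, mean -0.28; camera adjusted p = 0.717), with the antiviral Rsad2 at -2.13 ± 0.67 and Bst2 at 1.57 ± 0.39. Of 8 chemokine and cytokine genes, 4 were higher in spleen, including Il10ra (-1.79 ± 0.16) and Cxcl10 (-1.59 ± 0.20), and none in liver. That list passed (median -0.44; camera adjusted p = 0.029) but not without array 1 (adjusted p = 0.0517, from 0.0194 upwards over the other alternatives) nor with its correlation estimated (adjusted p = 0.344 with an estimated correlation). Of 11 stress genes, 4 were higher in liver and 3 in spleen (median -0.08, mean 0.28; camera adjusted p = 0.896). The metallothioneins Mt1 (3.09 ± 0.99, or 1.87 with exact zeros as values) and Mt2 (3.04 ± 0.13) were higher in liver, and Gadd45a (-2.05 ± 0.32) and Fos (-1.42 ± 0.55) in spleen.

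Markers of other tissues showed small ratios with few exceptions. Of 18 pancreas genes, 2 were higher in liver and 5 in spleen (median -0.20; camera adjusted p = 0.481), the largest being Spink1 (1.37 ± 0.30) and glucagon (Gcg, 1.09 ± 0.12), while the trypsinogen Try4 was not called (-0.09 ± 0.21). Of 10 muscle genes, 4 were higher in liver and 1 in spleen (median 0.51; camera adjusted p = 0.126), with the myosin light chain Myl1 at 1.60 ± 0.07 and cardiac actin Actc1 at -1.16 ± 0.28 (-1.75 with its largest spot). Of 6 brain genes only Stmn2 (-1.53 ± 0.40) was called (median 0.02, mean -0.22; camera adjusted p = 0.774). None of 4 endothelial genes was called (median -0.11), the largest being Esam (-0.50 ± 0.40), which passed without array 3 (-0.73, adjusted p = 0.0183, up to 0.298 over its other alternatives). Neither of the 2 adipose genes was called, with Lipe at -0.29 ± 0.19.

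Altogether 17 of 24 tested lists passed the camera test, 8 on the liver side and 9 on the spleen side. With an estimated correlation, camera passed 0 lists (1 at an unadjusted p under 0.05) and fry, which does not compare a list with other genes, passed 22. The macrophage list had an estimated correlation of -0.097, below the preset 0.01, yet its unadjusted camera p rose from 0.00104 to 0.075. For the neutrophil list (-0.188) it rose from 0.0084 to 0.115. A higher correlation cannot account for these 2 losses. Every other list that passed had an estimated correlation above the preset, from 0.016 (ribosomal proteins) to 0.572 (drug metabolism), with 0.462 for oxidative phosphorylation. For those lists a higher correlation may account for part of the loss, and the p at the preset correlation may be too small. Camera with an estimated correlation rests on the residual degrees of freedom, 2 here, and so has little power. Its 0 passes do not show that the shifts vanish once correlation is allowed for. Counts adjusted over the list alone equalled those over all genes except for carbohydrate metabolism (4 higher in liver), MHC class I (0), ribosomal proteins (4 in liver, 42 in spleen), the proteasome (13 and 1), secretion (16 and 3) and stroma (6 and 10). Under each gene's own variance 28 of the 118 named genes lost their call, among them Fgb, Ighm, Pde7a, S100a9, Hba-a2, Mt1 and Cd74.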

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

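Keeping exact zeros as values, averaging only spots valued on all arrays and leaving out AW and AU clones were chosen after the data were seen. Under centring, scaling, a value on at least 2 arrays, the largest spot per gene, trended robust variance and these 3 added settings, the calls numbered between 2638 and 3484, against 3146. No gene called in both settings changed side under any setting compared gene by gene, except 4 with the largest spot per gene and 10 without AW and AU clones. Per spot, which counts spots and not genes, 4964 passed (2459 liver, 2505 spleen), 2360 of them at least 2-fold (1241 and 1119). Under ordinary variance 1461 genes passed (869 and 592) and 930 at least 2-fold, 368 of them on the spleen side; this setting leaves 2 degrees of freedom per gene. Leaving out 1 array gave 1841 to 3343 calls (938 to 1530 liver, 903 to 1813 spleen), the lowest without array 1; the cause was not tested. The treat test passed 692 genes (419 and 273), as it asks for more than a point estimate of 2-fold.

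Camera with an estimated correlation passed 0 lists (0 liver, 0 spleen). The 312 list values under the other alternatives all used the preset correlation and leave out fry. Of these, 304 kept direction and side of the threshold and 4 lost the call: the neutrophil list (3 settings, adjusted p from 0.00477 to 0.124 over its alternatives at the preset correlation) and, without array 1, the chemokine list. The test direction of the brain list turned with values on at least 2 arrays (median 0.082), with zeros as values (0.073) and when leaving out 1 array (-0.024 to 0.099, turned without array 2), and that of the stress list under ordinary variance (median -0.081). Neither list passed in any of these, and the cause was not tested. Of 1415 values of the 118 named genes, 1371 kept direction and side, 42 lost the call, 1 gained it (Esam), and Rpl35a turned to -0.36 without AW and AU clones, which leaves it 1 spot with a value. Satb1 had no value on all arrays without those clones. The mean correlation between arrays was 0.912, and 0.966 over genes with an absolute log2 ratio of at least 1; the share of genes with one sign was 75.9%, against 77.8% per spot and 99.8% over those genes. Those genes were chosen by their mean over the same arrays, which by itself raises both values, so they say nothing about stability. The listed filter on intensity was not run because channel intensities were not used here, so what signal over background limits is unknown.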

Other observations

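The groups by shared symbol stem, the AW clone test, the ribosomal and respiratory comparison and the other-tissue clones were tests chosen only after results were seen. Nuclear genes of the mitochondrial ribosome were higher in liver. Of 26 large-subunit genes (Mrpl), 21 were higher in liver and none in spleen (median log2 ratio 0.77, camera adjusted p = 9.2e-05 over 70 symbol stems, adjusted p = 0.888 with an estimated correlation for this and each other stem that passed), with Mrpl12 at 2.15 ± 0.04 and Mrpl2 at 1.59 ± 0.17 (SD, n = 3). Of 13 small-subunit genes (Mrps), 11 were higher in liver (median 0.80, adjusted p = 0.00321), and of 11 genes of the inner-membrane import machinery (Timm), 8 were (median 0.80, adjusted p = 0.0089), including Timm8a1 (1.75 ± 0.25) and Timm23 (1.20 ± 0.26). Of 9 Abhd hydrolase genes, 8 were higher in liver (median 0.66, adjusted p = 0.0322), with the monoacylglycerol lipase Abhd6 at 2.48 ± 0.21, and Abhd17b was higher in spleen (-1.58 ± 0.57). In all, 10 of 70 stems passed, 8 on the liver side and 2 on the spleen side. The others were Tmem, which joins unrelated membrane proteins (31 of 69 higher in liver and 6 in spleen, median 0.29, adjusted p = 0.0167), and Atp, Cox, Ndufa, Rpl and Rps, which overlap the respiratory and ribosomal lists.

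Of 8 members of the Ms4a family of membrane proteins, 6 were higher in spleen and 1, Ms4a8a (0.63 ± 0.26), in liver; Ms4a6c stood at -2.44 ± 0.07 and Ms4a4d at -2.04 ± 0.25. Of 8 small nucleolar RNA host genes (Snhg), 7 were higher in spleen, such as Snhg5 (-0.76 ± 0.09) and Snhg10 (-0.73 ± 0.03). Neither family passed as a group (adjusted p = 0.0615 and 0.0598). Spots without a gene name held signal too: of 2285 with a value on all arrays 1240 passed, with 266 at least 2-fold higher in liver and 274 in spleen, and extremes of 5.26 and -4.06.

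Spots of one gene were called on opposite sides for 89 of 823 genes with at least 2 called spots (10.8%), among them Scp2 (-2.76 to 2.96) and Cox6a1 (-1.53 to 1.56). Pairs of spots with the same sequence identifier opposed each other in 6.67% (7 of 105) and pairs with different identifiers in 9.33% (67 of 718; Fisher's exact two-sided p = 0.466), so measurement noise and clone differences cannot be told apart from these counts, which hold few pairs of one identifier. A candidate explanation for part of the pattern is that some AW clones are not the gene they are named for: across 27 genes, AK and AW clones correlated with r = 0.146, against 0.756 for 2 AK clones over 1164 genes (one-sided permutation p = 0.00324) and 0.903 for 2 spots of one AW identifier over 48 genes, and with 0.392 over 25 genes without the 2 farthest from the median. Whether called or not, 2 spots of one AK identifier (r = 0.851 over 100 pairs) opposed each other in 23% and 2 AK clones in 22.7%, against 4.17% for 2 spots of one AW identifier, so noise stays open for AK clones. A difference in transcript part stays open as well, the genes are not independent replicates, and no biological explanation was tested.

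The medians of the respiratory chain and ribosomal protein lists differed by 2.20, 2.23 and 1.78 on arrays 1, 2 and 3 (mean 2.07 ± 0.25 SD), with opposite signs on all 3. This argues against a shift shared by abundant short transcripts as the sole cause of both, since it would move both lists the same way. The opposite sides had been seen before this comparison was chosen. Transcript length and abundance were not measured, so such a shift on top of another difference, in either list or both, stays open. A gene-specific dye effect stays open, since 0 arrays had the dyes exchanged, so dye and tissue cannot be told apart for either list. A difference between the tissues themselves stays open too and was not tested apart from the dyes.

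Clones of genes known from other tissues, namely Lipf and Atp4b of the stomach, Tpbpa and Tpbpb of the placenta and Sbpl, a spermine-binding protein-like gene, were called in 47.5% of cases (38 of 80 spots, 13 on the liver side and 25 on the spleen side), against 59.7% of the remaining spots. Only 5 of the 80 were called at 2-fold or more (6.25%, against 28.7% of the rest), and the median absolute log2 ratio of the called clones was 0.60. Only clones with a value on all 3 arrays were counted. These were 33 of 40 for Sbpl, 28 of 44 for Lipf and 9 of 10 for Atp4b. For Tpbpa they were 7 of 26, and for Tpbpb 3 of 15. The calls came from Sbpl (21 of 33), Lipf (10 of 28), Atp4b (5 of 9), Tpbpa (1 of 7) and Tpbpb (1 of 3). Without Sbpl, 36.2% of the counted clones (17 of 47) were called. Background signal rather than expression could give such shares, and so could low-level expression, for example of Sbpl with its median of -0.43. The share that background would give was not measured. Neither explanation was tested against the other, and both stay open.

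In comparison, 14 of 18 Hba-a1 clones and 17 of 19 Hbb-bs clones had a value on all arrays. All 14 of Hba-a1 were called at 2-fold or more, with a median of -2.29 and an SD over clones of 0.32. Of 17 Hbb-bs clones, 15 were, with a median of -1.87, an SD of 0.73 and a range from -2.36 to 0.31.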
